A study of Mus musculus with 12 samples.

How the data were processed

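Poly(A) RNA of bone-marrow-derived macrophages was sequenced as paired ends on an Illumina NovaSeq instrument by the authors, in 12 libraries of 4 groups with 3 libraries each: WT control, WT LPS, KO control and KO LPS. Each library was mapped to its group by the sample titles and the column names of the table, and no column was left unmapped. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 and the genome builds mm8 and mm9, without saying which tool or build made which value. The counting tool, the annotation release and any filter are not stated, and neither is whether reads were assigned by strand. The table gives Ensembl gene identifiers and symbols and no coordinates, so no positions are printed; GENCODE M21 was used only for the order of genes along chromosomes, their types and their overlaps, and held 27529 of the 27603 identifiers (99.7%).

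The deposited table holds, per the column headers, a count and an FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library and computed by the authors) for each gene and library. The deposited counts are whole numbers and sum to between 66050846 and 77123933 per library. After terms for gene and library were removed, the log2 ratio of count to FPKM had an SD of 0.000789, and low counts piled up at multiples of 4 (10771 entries equal to 4, against 9346 equal to 1, 7161 equal to 2 and 5451 equal to 3). Counts computed from read coverage have these properties, so a small count may rest on fewer fragments than its size. Pairs of replicates differed more than counting error alone gives (chi-square per degree of freedom between 3.04 and 6.73), so no library is a copy of another. The floor for a count of 0 uses 3 fragments at an assumed 4 counts each and covers counting error only, as PCR copies are not independent molecules.

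The groups, comparisons, tests, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. The plan named limma on log2(FPKM + 1) as the test unless the table held raw counts, in which case edgeR on the counts. As the table held whole-number counts, edgeR was used. Counts with the properties above may not be raw, so it is uncertain that the condition of the plan was met. limma on log2(FPKM + 1) is given among the alternatives. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17083 of 27603 genes. Libraries were scaled by TMM and fitted with 1 mean per group by the quasi-likelihood pipeline of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, common biological coefficient of variation 0.141) in R 4.3.3. The 6 contrasts tested were: LPS against control in each genotype, KO against WT without LPS, with LPS and averaged over both treatments, and the difference in LPS response. P-values were adjusted by Benjamini-Hochberg over all genes tested within a contrast, with a threshold of 0.05. LPS against control in WT and in KO share no libraries; the other contrasts share libraries with these. With 3 libraries against 3 an exact permutation test cannot go below 0.1, so single genes rest on the pooled model. The labels do not say whether the number of a replicate pairs libraries, and no pairing was modelled. Residuals of libraries with the same number had correlations across genes between -0.038 and 0.042. These gave no sign of pairing but cannot exclude it.

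Genes were named by the rule fixed beforehand. Otud6a, Nlrp3, Il1b, Casp1, Pycard, Gsdmd, Il18, Tnf, Il6, Nos2, Ifnb1 and Il10 are given wherever useful. In 4 comparisons (LPS in WT, and KO against WT without LPS, with LPS and over both treatments) the 8 genes with the largest rise and the 8 with the largest fall are named among those past the threshold, without overlap between the libraries of the groups and with a mean of at least 5 FPKM in the higher group, leaving out predicted genes; some genes that meet these rules are not reported here. For the difference in LPS response it is the 6 largest in each direction under the same conditions apart from overlap. For each gene list up to 4 members with the smallest adjusted p can be named. In all 31 lists with 696 entries were fixed, of which 684 entries were in the table and 645 were tested; 29 lists had at least 5 tested members. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the lists within a contrast), which compares a list with all other genes, and again with an estimated correlation.

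The alternatives chosen beforehand were no filter on low values, a filter of at least 5 FPKM in at least 3 libraries, median-of-ratios size factors, the replicate number as a block, a robust variance model, fits of only the groups compared, DESeq2 1.42.0, and limma on log2(FPKM + 1), on log2(FPKM + 0.1), on quantile-normalized and on size-factor-scaled values (FPKM of at least 1 in at least 3 libraries), and leaving out each library in turn. Added after the data were seen were counts divided by 4, fits without the genes of chromosome Y and of a crowded stretch of chromosome 8, and the agreement of responses over well-counted genes. The pipeline was tested on simulated counts with the means, spread and library sizes of the data, no genotype effect and planted changes in KO LPS. edgeR called 34% of planted genes at 1.25-fold, 30% at 1.5-fold, 64% at 2-fold and 84% at 4-fold, each in the right direction, and 3 of its 133 calls (2.26%) were false. limma, run on size-factor-scaled log2(FPKM + 1) of 11402 genes, made 15 false calls of 133 (11.3%) and DESeq2 22 of 163 (13.5%). The counts were drawn from the means and spread that edgeR had fitted, without the pile-up at multiples of 4. These rates therefore cannot rank the tools. The set test found the planted list and none of 40 null lists. The simulated genes were drawn independently, so this does not test the preset correlation on lists whose genes vary together. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.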

Results

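RNA was sequenced from bone-marrow-derived macrophages of wild-type (WT) C57BL/6 mice and of mice lacking Otud6a (KO), a gene for a deubiquitinase of the OTU family. The marrow cells matured in medium conditioned by L-929 fibroblasts, a source of macrophage colony-stimulating factor, and were used on day 7 at 300000 cells per well. Cells of each genotype received phosphate-buffered saline (control) or lipopolysaccharide (LPS), the bacterial ligand of Toll-like receptor 4 (TLR4), at 100 ng/mL for 6 h. The 4 groups (WT control, WT LPS, KO control and KO LPS) held 3 libraries each, described by the series as biological replicates. Whether each came from its own animal is not stated, so the p-values below may in part measure the spread between cultures of one animal. The title of the series links OTUD6A in macrophages to the NLRP3 inflammasome and to colitis.

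The deposited gene table held 27603 genes. The WT control libraries summed to 74179917, 77123933 and 72766199 counts, the WT LPS libraries to 71866884, 72598169 and 71711602, the KO control libraries to 70192357, 74539375 and 74025921 and the KO LPS libraries to 70433712, 66050846 and 69199433. Between 19216 and 20571 genes had a count in each library. The first principal component carried 67.2% of the variance and parted LPS from control libraries. The second carried 6.32% and parted KO from WT in both treatments. On the first component KO LPS replicate 3 (score 98.2) lay nearer to the WT LPS libraries (106 to 108) than KO LPS replicates 1 and 2 did (78.6 and 81.9). Of the genes, 17083 had enough counts for the test (edgeR quasi-likelihood, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Levels are given as mean FPKM ± SD with n = 3 libraries, and changes as log2 values from the normalized counts with their standard error (SE). The deposited FPKM were not rescaled for library composition, and in them LPS moved the median log2(FPKM + 1) of all genes by -0.58 in WT and by -0.48 in KO; the log2 changes from the normalized counts are relative to that shift.

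Otud6a (ENSMUSG00000051582, chromosome X), the targeted gene, was almost undetected in macrophages of both genotypes. WT control replicate 3 held 7 counts, WT LPS replicate 1 held 4, KO LPS replicate 1 held 4 and the other 9 libraries held 0. The highest level was 0.0905 FPKM. A count of 0 allows up to 3 fragments per library. At an assumed 4 counts per fragment this is 12 counts or 0.156 to 0.182 CPM (counts scaled to a common library total). With all libraries under that floor, Otud6a was below the filter of the test, no fold change between genotypes was computed, and the loss of the gene could not be checked at this depth.

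LPS against control in WT cells gives the normal response to TLR4 stimulation. It turned on the inflammatory programme of WT macrophages. Il6, which encodes interleukin-6, went from 0.194 ± 0.0469 to 132 ± 4.49 FPKM (log2 change 10.03, SE 0.0845). Il12b, the p40 subunit shared by interleukin-12 and interleukin-23, went from 0.333 ± 0.0839 to 215 ± 12.6 FPKM (9.99), and Nos2, the inducible nitric oxide synthase, from 0.853 ± 0.178 to 449 ± 12.1 FPKM (9.72). The inflammasome sensor Nlrp3 (ENSMUSG00000032691) rose from 10.6 ± 0.805 to 74.0 ± 2.53 FPKM (3.48, SE 0.0568), and Il1b, whose product caspase-1 cleaves, from 0.956 ± 0.269 to 254 ± 17.0 FPKM (8.73). Casp1 (2.46), the pore-forming Gsdmd (1.84), Il18 (4.73), Tnf (4.06), Ifnb1 (6.03) and the anti-inflammatory Il10 (5.51) rose as well, with adjusted p-values between 8.73e-17 and 3.43e-07. Pycard, the inflammasome adaptor ASC, had a log2 change of -0.068 (SE 0.0676, adjusted p = 0.412), which missed the threshold and was 0.0026 without WT LPS replicate 3. It passed as lower with at least 5 FPKM in at least 3 libraries (-0.18), on quantile-normalized values (-0.23) and in limma on log2(FPKM + 1) (-0.68) and on log2(FPKM + 0.1) (-0.75). Its FPKM, not corrected for composition, were 12.4 ± 0.188 and 7.39 ± 0.806.

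In this comparison 10677 of 17083 genes passed the test, 5093 higher and 5584 lower with LPS, and 5292 of them changed at least 2-fold (2669 up, 2623 down). Beside Il6, Il12b and Nos2, the 8 largest rises among genes of at least 5 FPKM were those of the interferon-inducible chemokine gene Cxcl11 (9.60), U90926 (9.51), the endothelin precursor gene Edn1 (9.43), BC023105 (9.21) and Csf3, which encodes granulocyte colony-stimulating factor (9.10). U90926 and BC023105 were at 0 in 2 of the 3 WT control libraries, so their fitted changes depend on the prior count. The 8 largest falls were those of the cell-division gene Cdca7 (-5.69), the stress-inducible sestrin Sesn1 (43.0 ± 1.65 to 0.670 ± 0.0397 FPKM, -5.31), Pald1 (-5.00), Nanos1 (-4.96), the cannabinoid receptor gene Cnr2 (-4.67), the sterol carrier gene Stard4 (-4.61), the myeloid transcription factor gene Cebpa (14.6 ± 1.099 to 0.402 ± 0.0291 FPKM, -4.49) and the lipid desaturase gene Scd2 (-4.25). For each of these 16 genes the 3 LPS libraries did not overlap the 3 control libraries. The rule for naming required this, so it adds no support. By chance it happens for 10% of genes in each comparison of 3 with 3. Cxcl11, Edn1 and Sesn1 overlap other annotated genes, and the deposited files do not say whether reads were assigned by strand, so part of their counts can belong to the neighbours.

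Of the gene lists fixed in advance, 14 of 29 passed the set test (camera) in this comparison, 6 of them also with an estimated correlation between genes. Of 43 measured NF-kB inflammatory targets 41 rose and 0 fell (median log2 change 4.09, adjusted p = 8.51e-110 for the list), among them the chemokine genes Ccl5 (7.53) and Ccl3 (5.17) and the cytokine gene Il1a (8.79). All 46 measured interferon-stimulated genes rose (median 4.16), such as the GTPase gene Gbp2 (6.59) and the chemokine gene Cxcl9 (8.69). The list had an adjusted p of 5.93e-34, and adjusted p = 0.114 with an estimated correlation. Of 22 negative regulators of TLR signalling 21 rose (median 2.68, adjusted p = 1.66e-34), among them Socs3 (7.13), a brake on cytokine receptors, and Zfp36 (3.93), which destabilizes cytokine mRNA. Of 22 inflammasome genes 15 rose and 4 fell (median 2.05, adjusted p = 2.19e-20), of 24 immediate early genes 19 rose and 1 fell (1.84, 2.26e-09), and of 12 genes of MHC class II and co-stimulation 7 rose and 2 fell, or at most 1 fell with any 1 library left out (0.63, 5.32e-05), with Cd40 at 6.20 and Cd274 at 5.38. Of 21 genes of chemokine receptors and migration 13 rose and 3 fell (0.63, 4.76e-06). Counts of members adjusted over the list alone differed from these by at most 1 gene.

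Proliferation and sterol genes went the other way. Of 40 measured cell cycle genes 38 fell and 2 rose in WT cells (median -1.45; adjusted p = 3.23e-12, and adjusted p = 0.232 with an estimated correlation), including the replication helicase gene Mcm7 (-2.77). Of 24 cholesterol synthesis genes 23 fell and none rose (median -1.70; adjusted p = 1.06e-09, and adjusted p = 0.113 with an estimated correlation), including Mvd (-2.48). Of 18 glycolysis genes 12 rose and 2 fell (median 0.38), led by the regulator Pfkfb3 (4.37); the list had an adjusted p of 0.00113, and adjusted p = 0.0827 with an estimated correlation. Of 30 proteasome genes 23 rose and 1 fell (median 0.45, with the immunoproteasome gene Psmb10 at 2.70); here the adjusted p was 4.75e-04, and adjusted p = 0.454 with an estimated correlation. On quantile-normalized FPKM the set test turned to lower for both lists, with mean log2 changes of 0.041 for glycolysis and 0.030 for the proteasome. Of 14 heat shock genes 9 rose and 2 fell (adjusted p = 8.31e-04, and adjusted p = 0.109 with an estimated correlation), and of 29 components of the TLR4 pathway 19 rose and 7 fell (adjusted p = 2.16e-05, and adjusted p = 0.0607 with an estimated correlation). Of 13 OTU deubiquitinases 7 rose and 6 fell (3 fell without WT LPS replicate 2), led by Tnfaip3, which encodes an inhibitor of NF-kB (3.90); the list had an adjusted p of 0.0148, and adjusted p = 0.232 with an estimated correlation.

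The question in KO cells was whether the same response occurs without Otud6a. KO macrophages turned on the same inflammatory genes. Il6 went from 0.123 ± 0.0182 to 125 ± 3.97 FPKM (log2 change 10.52, SE 0.0890), Nlrp3 from 13.6 ± 0.704 to 80.2 ± 1.12 FPKM (3.14, SE 0.0558), Il1b from 0.603 ± 0.255 to 181 ± 5.61 FPKM (8.79) and Nos2 from 0.816 ± 0.196 to 448 ± 10.5 FPKM (9.68). Casp1 (2.45), Gsdmd (1.86), Il18 (4.94), Tnf (3.89), Ifnb1 (6.24) and Il10 (4.88) rose. In all, 10132 genes passed the test, 4920 higher and 5212 lower with LPS, and 4581 of them changed at least 2-fold (2397 up, 2184 down). Pycard had a log2 change of -0.20 (adjusted p = 0.0197); it missed the threshold without KO control replicate 2 (-0.17), KO LPS replicate 2 (-0.17) or KO LPS replicate 3 (-0.18).

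The same 14 of 29 lists passed in KO cells as in WT cells, 6 of them also with an estimated correlation. NF-kB inflammatory targets rose in 42 of 43 cases (median 3.89, adjusted p = 8.18e-114), inflammasome genes in 16 of 22 with 5 lower (2.08, 1.40e-23), and negative regulators of TLR signalling in 19 of 22 with 1 lower (2.38, 5.42e-33). All 46 interferon-stimulated genes rose (median 4.51; adjusted p = 7.93e-42, and adjusted p = 0.0794 with an estimated correlation). Cell cycle genes fell in 39 of 40 cases (median -1.43; adjusted p = 8.86e-15, and adjusted p = 0.147 with an estimated correlation), and cholesterol synthesis genes in 22 of 24 (median -1.31; adjusted p = 4.24e-07, and adjusted p = 0.137 with an estimated correlation). Glycolysis genes rose in 11 of 18 cases and fell in 3 (adjusted p = 0.00484, and adjusted p = 0.111 with an estimated correlation); their mean log2 change was 0.56 and turned to -0.048 on quantile-normalized FPKM. With an estimated correlation the call was also lost for components of the TLR4 pathway (adjusted p = 0.05004), OTU deubiquitinases (adjusted p = 0.257), heat shock (adjusted p = 0.0794) and proteasome genes (adjusted p = 0.295).

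**Figure D1:**
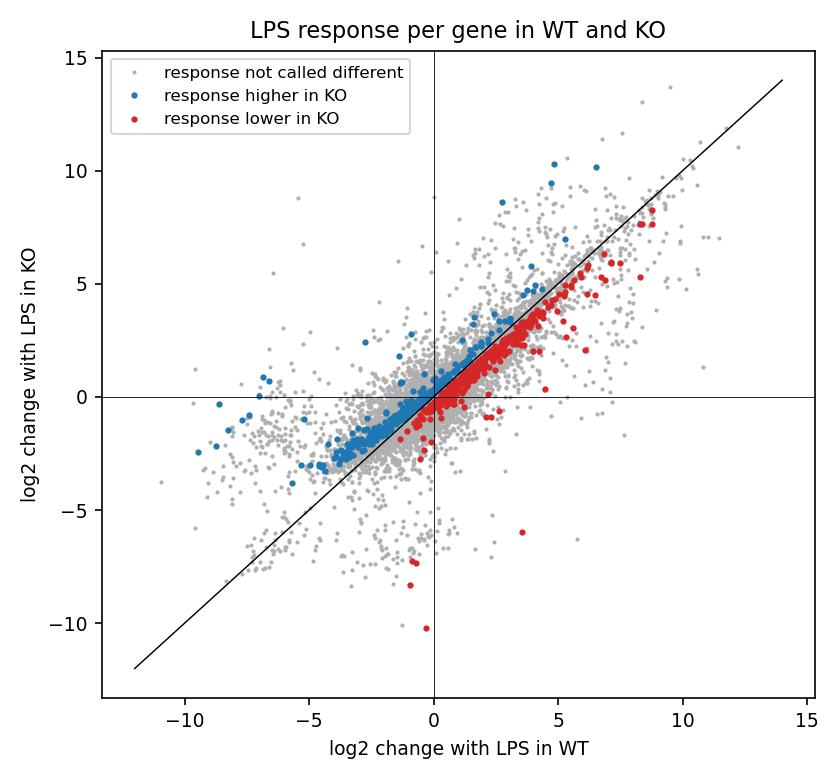
Each point is one of the 17083 tested genes, with its log2 change with LPS in WT cells on the horizontal axis and in KO cells on the vertical axis; blue and red points are the genes whose response passed the test as higher (343) or lower (486) in KO. The points follow the diagonal, and grey points far from it are genes with few counts.

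Across genes, the LPS responses of the genotypes, which share no libraries, had a Pearson r of 0.827, a Spearman rho of 0.866 and a slope of KO on WT of 0.764. Genes are not independent replicates, so no p-value is given. For the 8833 genes with a mean of at least 3 log2 CPM, a limit chosen after the values were seen, r was 0.979 and the slope 0.920. Of 9136 genes called in both genotypes, 9113 changed in the same direction, where independent calls would share 6333.

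KO against WT without LPS shows how the macrophages differed before stimulation. Among the genes of at least 5 FPKM that passed, the largest rise in KO was that of Hal (ENSMUSG00000020017, chromosome 10), which encodes histidine ammonia-lyase, an enzyme of histidine breakdown. It was at 0.294 ± 0.0587 FPKM in WT and 104 ± 3.07 FPKM in KO (log2 difference 8.46, SE 0.101, adjusted p = 1.01e-15). Next came a set of processed pseudogenes, retrocopies of spliced mRNA: Rps24-ps3 (5.24), Rpl3-ps2 (3.14), Rpl15-ps6 (2.97), Rpl3-ps1 (20.2 ± 0.420 to 151 ± 10.5 FPKM, 2.91), Rpl15-ps2 (2.75) and Tdg-ps2 (2.65). Their parents Rpl3 (-0.85), Rpl15 (-0.33) and Tdg (-1.78) were lower in KO. C1qtnf6 (1.94) was higher. Lower in KO were also the interferon-inducible GTPase gene Tgtp2 (-1.76), Nt5dc3 (-1.60), the fibrinogen-like gene Fgl2 (25.5 ± 0.998 to 10.1 ± 0.402 FPKM, -1.33), Tmem254c (-1.32), the macrophage surface gene Ms4a4a (-1.31) and the inhibitory receptor gene Pirb (73.1 ± 0.951 to 32.1 ± 0.690 FPKM, -1.18). The genes named by size of change showed no overlap between KO and WT libraries, as the rule for naming required. Tgtp2, Tdg, Fgl2 and Rpl15-ps2 overlap other annotated genes, and reads of a pseudogene can also come from its parent.

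In all, 1436 genes differed, 709 higher and 727 lower in KO, and 182 of them at least 2-fold (95 up, 87 down). Nlrp3 was higher in KO at 13.6 ± 0.704 against 10.6 ± 0.805 FPKM (log2 difference 0.36, SE 0.0529, adjusted p = 4.78e-04), and so was Tnf at 42.6 ± 1.74 against 32.8 ± 0.993 FPKM (0.38, adjusted p = 7.43e-05). Gsdmd was lower (-0.23, adjusted p = 0.00132). Il1b (-0.65, adjusted p = 0.123), Casp1 (-0.063, 0.653), Pycard (0.064, 0.747), Nos2 (-0.057, 0.938), Ifnb1 (-1.12, 0.580) and Il10 (0.0086, 0.987) did not pass. Il1b passed as lower without WT control replicate 3 (-0.83) or KO control replicate 2 (-0.99), and Ifnb1 without KO control replicate 1 (-4.92). Il18 (-0.58, 0.0124) and Il6 (-0.67, 0.0225) passed as lower, at 1.81 against 2.73 and 0.123 against 0.194 FPKM, but both calls were lost with any of 4 libraries left out in turn. Il18 missed the threshold without WT control replicate 1 (-0.51), WT control replicate 3 (-0.51), KO control replicate 2 (-0.50) or KO control replicate 3 (-0.51), and Il6 without WT control replicate 1 (-0.67), WT control replicate 2 (-0.49), KO control replicate 2 (-0.69) or KO control replicate 3 (-0.55). With only the groups compared both calls were lost (-0.58 and -0.66), and that of Il6 also with counts divided by 4 (-0.73) and in limma on log2(FPKM + 1) (-0.088), on quantile-normalized (-0.039) and on size-factor-scaled values (-0.070).

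Among the gene lists, 13 of 29 passed the set test without LPS, 2 of them also with an estimated correlation. The first of these was glycolysis, with 13 of 18 genes higher and 1 lower in KO (median log2 difference 0.26; adjusted p = 1.23e-14, and 0.00454 with an estimated correlation). The enzyme genes Eno1 (0.41), Pgam1 (0.36), Pfkl (0.39) and Ldha (0.36) led it. The second was macrophage identity, with 12 of 24 genes lower and 3 higher (median -0.17; adjusted p = 2.57e-10, and 0.0329 with an estimated correlation). Its members included Lgmn (-0.51), Aif1 (-0.90) and Adgre1, a surface marker of mature macrophages (-0.47).

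Other lists passed only with the preset correlation. Interferon-stimulated genes were lower in 20 of 46 cases without LPS, and in 30 when adjusted over the list alone (median -0.40; adjusted p = 7.81e-13, and adjusted p = 0.442 with an estimated correlation), for example Rtp4 (-0.53) and Ifi47 (-0.995). This count moved with single libraries: 33 without KO control replicate 1, 8 without KO control replicate 2, 9 without KO control replicate 3 and 9 without WT control replicate 3. Cholesterol synthesis genes were lower in 11 of 24 cases, 17 when adjusted over the list alone (median -0.34; adjusted p = 4.92e-08, and adjusted p = 0.169 with an estimated correlation), with Fdps at -0.48; the count fell to 4 without WT control replicate 3, 6 without WT control replicate 1, 5 without KO control replicates 1 or 2 and 7 without KO control replicate 3. Of 22 inflammasome genes 8 were lower and 1, Nlrp3, was higher (median -0.12; adjusted p = 0.00908, and adjusted p = 0.0848 with an estimated correlation); Il1rn, the interleukin-1 receptor antagonist (-0.40), and the DNA sensor Aim2 (-0.43) were among the lower ones. Of 43 NF-kB inflammatory targets 15 were higher and 5 lower (3 lower without KO control replicate 3; median 0.048; adjusted p = 0.00328, and adjusted p = 0.509 with an estimated correlation), with Marcksl1 (0.73), Nfkb2 (0.44) and Tnfaip3 (0.42) up and Ebi3 (-0.59) down.

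The set test also called 7 further lists. Negative regulators of TLR signalling were higher in 5 of 22 cases and lower in 1 (adjusted p = 1.42e-06, and adjusted p = 0.110 with an estimated correlation), with the phosphatase gene Dusp4 at 1.305 and Socs3 at 0.89. Immediate early genes were higher in 7 of 24 and lower in 1 (adjusted p = 0.0112, and adjusted p = 0.194 with an estimated correlation), with Fos at 0.50 and Myc at 0.44. Heat shock genes were higher in 7 of 14 (adjusted p = 3.62e-04, and adjusted p = 0.110 with an estimated correlation), with Hspa1b at 0.64. Genes of osteoclasts, the bone-resorbing cells of the macrophage lineage, were higher in 3 of 10 (median 0.18; adjusted p = 0.00135, and adjusted p = 0.0791 with an estimated correlation): the metalloproteinase gene Mmp9 (1.254), the cathepsin gene Ctsk (0.66) and the fusion gene Dcstamp (1.92). NRF2 targets were higher in 4 of 20 and lower in 2 (adjusted p = 0.0488, and adjusted p = 0.396 with an estimated correlation). Alternative activation genes were lower in 4 of 18 and higher in 1 (adjusted p = 0.0317, and adjusted p = 0.169 with an estimated correlation); their test and median (-0.13) were negative while their mean was 0.23, with the mannose receptor gene Mrc1 at -0.55 and Egr2 at 0.87. Cytosolic ribosomal protein genes were lower in 2 of 36, Rpl3 and Rpl15 (adjusted p = 0.00183, and adjusted p = 0.650 with an estimated correlation).

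**Figure D2:**
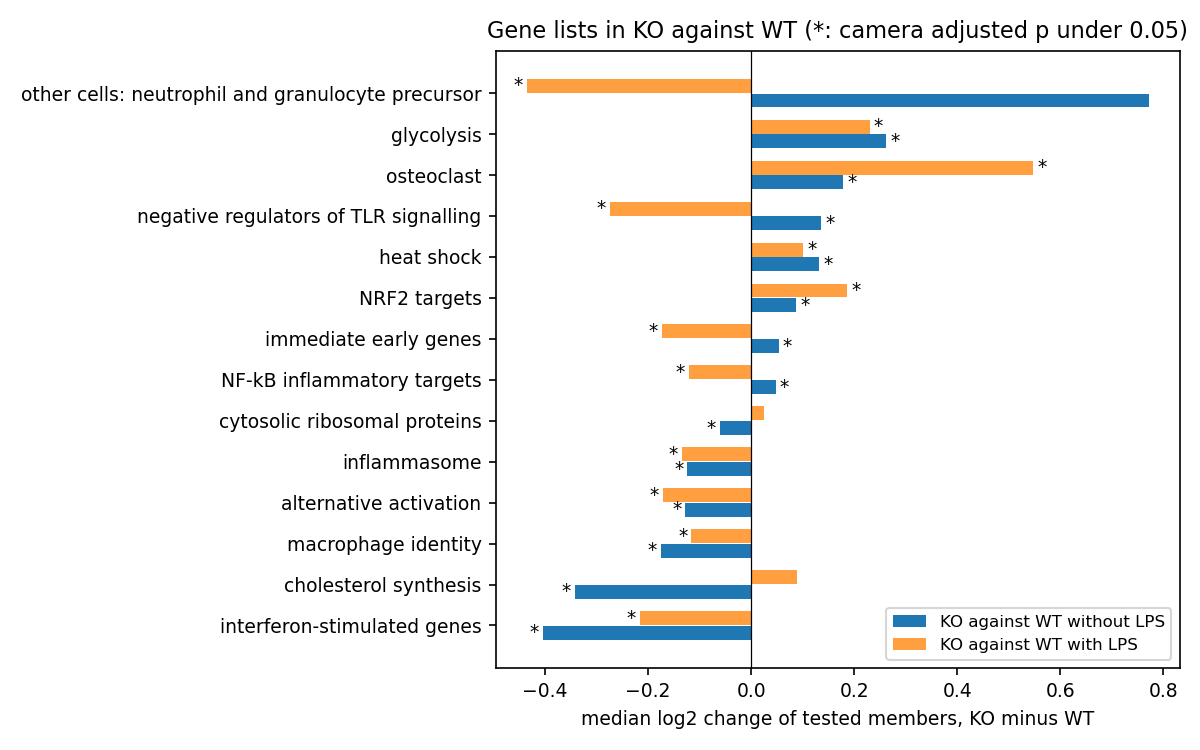
Bars give the median log2 difference between KO and WT over the tested members of each of the 14 gene lists that passed the set test without or with LPS; an asterisk marks a list whose adjusted p was below 0.05 with the preset correlation. The glycolysis median was 0.26 without and 0.23 with LPS, and that of interferon-stimulated genes -0.40 and -0.22.

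KO against WT with LPS asks how stimulated macrophages differed. Hal was again the gene most raised in KO (0.0907 ± 0.0183 to 24.2 ± 0.912 FPKM; log2 difference 7.94, SE 0.112, adjusted p = 9.75e-15). Timd4 (chromosome 11), which encodes a receptor for phosphatidylserine on dying cells, followed at 0.212 ± 0.122 against 23.5 ± 1.245 FPKM (log2 difference 6.67, SE 0.295, adjusted p = 3.21e-09). Also higher in KO were Rps24-ps3 (5.99), the autophagy regulator Depp1 (4.28), the actin-associated Pdlim4 (1.29 ± 0.150 to 13.6 ± 0.984 FPKM, 3.30), Rpl3-ps1 (3.02), Rpl3-ps2 (2.81) and Rpl15-ps6 (2.73). Lower in KO were Olfr56 (34.9 ± 0.735 to 2.01 ± 0.974 FPKM, -4.20), an olfactory receptor gene whose annotation overlaps the interferon-inducible GTPase gene Ifi47 on the same strand, the angiopoietin gene Angpt1 (6.50 ± 0.261 to 0.630 ± 0.118 FPKM, -3.46), Mid1-ps1 on chromosome Y (-2.79), Tdg (-2.39), the signal-regulatory receptor genes Sirpb1a (-1.89) and Sirpb1b (-1.87) and Mtus1 (-1.68). KO and WT libraries did not overlap for any of these genes, as the rule for naming required. Depp1, Mid1-ps1, Mtus1 and Sirpb1b overlap other annotated genes.

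With LPS 2526 genes differed, 1267 higher and 1259 lower in KO, and 325 of them at least 2-fold (209 up, 116 down). Several cytokine genes were lower in KO: Il12b at 89.0 ± 6.17 against 215 ± 12.6 FPKM (log2 difference -1.36, SE 0.0855, adjusted p = 1.23e-07), Il10 at 86.9 ± 3.41 against 125 ± 8.63 FPKM (log2 difference -0.62, SE 0.0672, adjusted p = 2.54e-05) and Il1b at 181 ± 5.61 against 254 ± 17.0 FPKM (log2 difference -0.59, SE 0.122, adjusted p = 0.00459). The Il1b call was lost in DESeq2 (-0.60) and in limma on log2(FPKM + 0.1) (-0.49). Gsdmd was lower (-0.21, adjusted p = 0.00163) and Tnf higher (0.21, adjusted p = 0.00505). Nlrp3 was at 80.2 ± 1.12 FPKM in KO and 74.0 ± 2.53 in WT, which after normalization was a log2 difference of 0.02 (adjusted p = 0.865). Casp1 (-0.072, 0.445), Pycard (-0.069, 0.603), Nos2 (-0.10, 0.650) and Ifnb1 (-0.91, 0.203) did not pass. Ifnb1 passed as lower with counts divided by 4 (-0.90), with only the groups compared (-0.89), in DESeq2 (-0.92) and in limma on log2(FPKM + 1) (-0.57), on quantile-normalized (-0.65) and on size-factor-scaled values (-0.69). Il18 (-0.38, 0.0234) and Il6 (-0.18, 0.0284) passed as lower. The Il18 call was lost without any one of WT LPS replicates 1 (-0.39), 2 (-0.33) or 3 (-0.39) and KO LPS replicates 1 (-0.38) or 2 (-0.36), and the Il6 call without WT LPS replicates 1 (-0.16) or 2 (-0.16) or KO LPS replicates 1 (-0.16), 2 (-0.18) or 3 (-0.17). Both were lost in limma on log2(FPKM + 1) (-0.27 and -0.077), on log2(FPKM + 0.1) (-0.28 and -0.078) and on quantile-normalized values (-0.27 and -0.0999), and that of Il6 also with no filter on low values (-0.17).

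**Figure D3:**
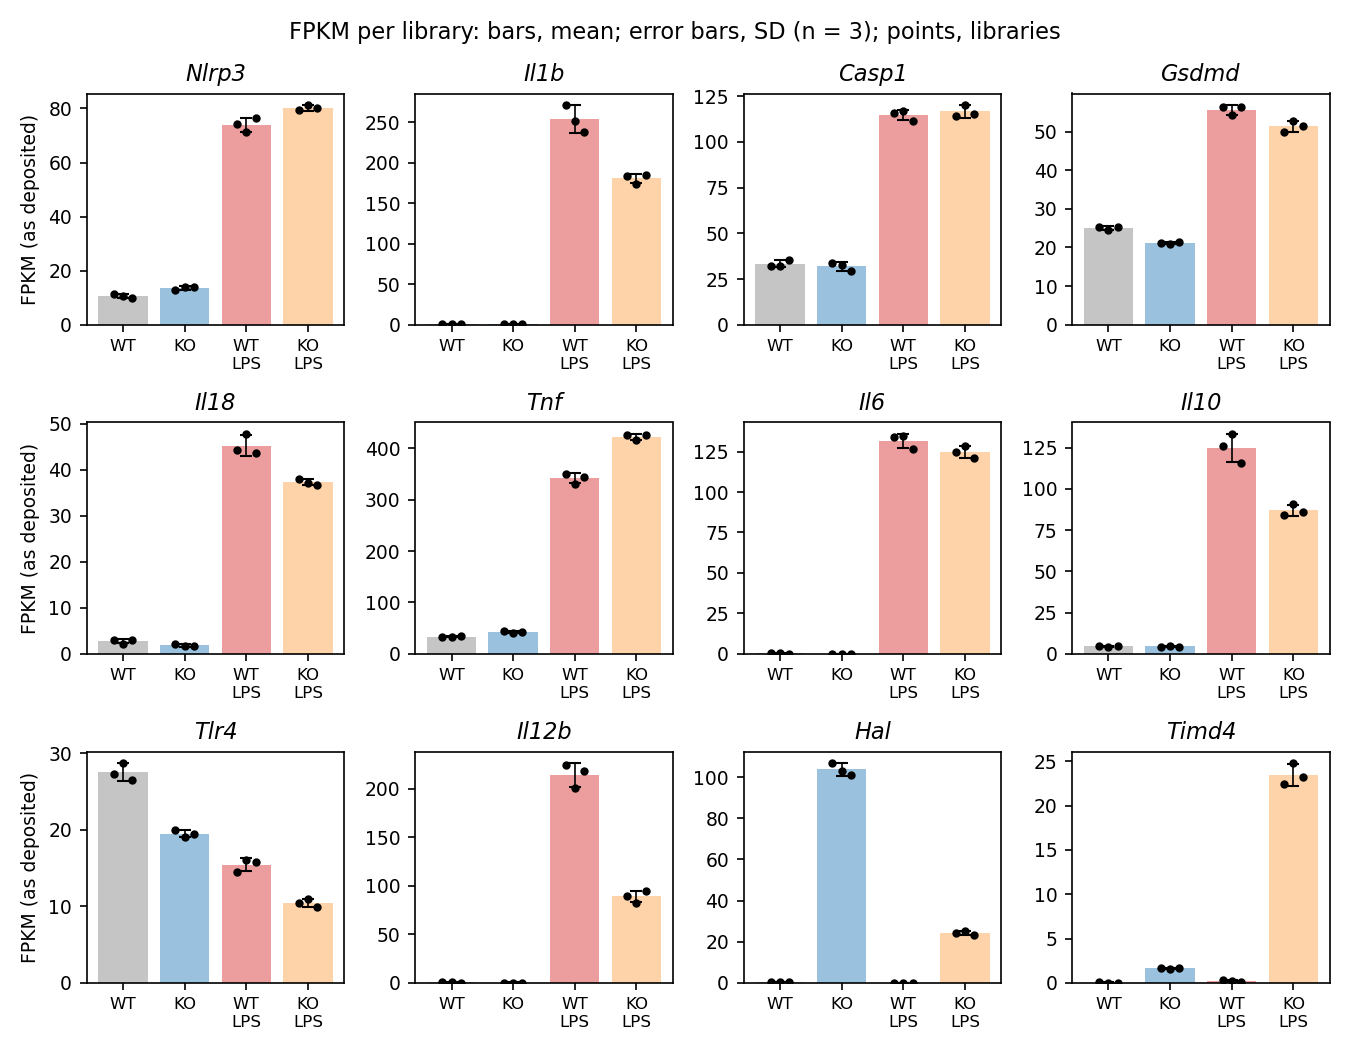
Bars show the mean FPKM of the 3 libraries of each group, error bars the SD and points the single libraries, for 12 genes of the report. With LPS, Il12b, Il10 and Il1b are lower in KO libraries while Hal and Timd4 are higher.

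None of the 12 gene lists that passed with LPS also passed with an estimated correlation. Of 43 NF-kB inflammatory targets 19 were lower in KO and 2 higher, 22 and 2 when adjusted over the list alone (median -0.12; adjusted p = 2.95e-07, and adjusted p = 0.167 with an estimated correlation). Beside Il12b these included Ebi3 (-0.61), the prostaglandin synthase gene Ptgs2 (-0.77) and Il1a (-0.55). Negative regulators of TLR signalling were lower in 11 of 22 cases and higher in 1, Dusp4 at 1.57 (median -0.27; adjusted p = 0.00347, and adjusted p = 0.282 with an estimated correlation). Inflammasome genes were lower in 10 of 22 and higher in 2 (median -0.13; adjusted p = 0.00533, and adjusted p = 0.0827 with an estimated correlation). Immediate early genes were lower in 8 of 24 and higher in 1 (adjusted p = 0.0112, and adjusted p = 0.167 with an estimated correlation), with Egr1 at -1.03. Interferon-stimulated genes were lower in 5 of 46 (median -0.22; adjusted p = 4.87e-04, and adjusted p = 0.741 with an estimated correlation), with Cxcl11 at -0.76; only 1 was lower without WT LPS replicate 1 or KO LPS replicate 1, and 3 without WT LPS replicate 2, WT LPS replicate 3 or KO LPS replicate 2.

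Lists with higher members in stimulated KO cells were NRF2 targets, with 14 of 20 higher (median 0.19; adjusted p = 6.88e-06, and adjusted p = 0.0827 with an estimated correlation), for example the thioredoxin reductase gene Txnrd1 (0.38) and Gclm (0.41); glycolysis, with 11 of 18 higher and 4 lower (median 0.23; adjusted p = 4.87e-04, and adjusted p = 0.0913 with an estimated correlation), Eno1 at 0.46 but Pfkfb3 at -0.56; heat shock, with 6 of 14 higher (adjusted p = 0.00255, and adjusted p = 0.159 with an estimated correlation); and osteoclast genes, with 5 of 10 higher, or 3 without WT LPS replicate 3 (median 0.55; adjusted p = 7.31e-04, and adjusted p = 0.0827 with an estimated correlation), Ctsk at 0.87 and Dcstamp at 3.17. Macrophage identity genes were lower in 11 of 24 cases and higher in 3, or as few as 1 (without WT LPS replicate 1; median -0.12; adjusted p = 8.77e-04, and adjusted p = 0.159 with an estimated correlation); the chemokine receptor gene Cx3cr1 was among the higher ones (0.80). Alternative activation genes were lower in 6 of 18 (adjusted p = 0.0204, and adjusted p = 0.159 with an estimated correlation). Markers of neutrophils and their precursors, cells that bone marrow also holds, were lower in 2 of 6 tested, Csf3r (-0.45) and Mmp8 (-0.42), with a median of -0.43 and a mean of 0.11 of the opposite sign (adjusted p = 0.0493, and adjusted p = 0.162 with an estimated correlation). The marker lists of dendritic cells, lymphocytes, stromal cells and erythroid cells did not pass between genotypes.

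Whether the LPS response itself differed between genotypes was tested as an interaction. Some genes repressed by LPS in both genotypes fell less in KO. Sesn1 fell by 5.31 on the log2 scale in WT and by 3.02 in KO (log2 difference 2.30, SE 0.393, adjusted p = 0.00401), Cdca7 by 5.69 and 3.80 (difference 1.90), Stard4 by 4.61 and 3.05 (difference 1.57). The Cdca7 call was lost in limma on log2(FPKM + 1) (0.26), on quantile-normalized (0.38) and on size-factor-scaled values (0.30). Pdlim4 (1.94, adjusted p = 4.32e-06) and Rab3il1 (1.49) also had more positive responses in KO. The responses of Timp1, an inhibitor of metalloproteinases (-2.54), Olr1, a receptor for oxidized lipoprotein (-1.63), the matrix gene Tnc (-1.56) and the amino acid transporter gene Slc7a2 (-1.43) were more negative in KO, with adjusted p-values from 6.13e-06 to 9.23e-04. In all, the response of 829 genes differed, with 343 more positive and 486 more negative in KO and 106 of them by at least 2-fold (65 and 41). Without KO LPS replicate 1 the number was 518. Timp1, Sesn1 and Tnc overlap other annotated genes.

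Nlrp3 rose by 3.48 in WT and 3.14 in KO on the log2 scale (log2 difference -0.34, SE 0.0735, adjusted p = 0.0168), starting from the higher level of KO control cells. This call was lost without WT LPS replicate 3 (-0.30), without KO LPS replicate 1 (-0.31) and in limma on log2(FPKM + 1) (-0.21), on log2(FPKM + 0.1) (-0.23) and on quantile-normalized values (-0.28). Il10 rose less in KO (log2 difference -0.63, SE 0.108, adjusted p = 0.00401). Rps27rt, a ribosomal retrogene, and Angpt1 had the most extreme values, 3.16 (adjusted p = 0.0340) and -2.98 (adjusted p = 0.0366), but missed the threshold in most fits with 1 library left out and in other settings. Both missed it with no filter on low values (3.16 and -2.98) and with the robust variance model (3.16 and -2.98), Rps27rt also with the replicate number as a block (3.07) and in limma on log2(FPKM + 0.1) (3.08), on quantile-normalized (2.75) and on size-factor-scaled values (2.88), and Angpt1 with counts divided by 4 (-2.88) and in DESeq2 (-2.97). With 1 library left out, Rps27rt missed it without WT control replicates 2 (3.17) or 3 (2.52), any WT LPS replicate (2.91 to 3.37), KO control replicates 2 (2.84) or 3 (2.99) or KO LPS replicate 1 (2.94). Angpt1 missed it without WT control replicates 1 (-2.54) or 2 (-3.21), any WT LPS replicate (-2.99 to -2.94), KO control replicates 2 (-2.28) or 3 (-2.84) or KO LPS replicates 1 (-2.89) or 2 (-2.89).

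Of the lists, 8 of 29 passed for the interaction, 2 of them also with an estimated correlation; without WT LPS replicate 2, 13 passed. Negative regulators of TLR signalling had smaller responses in KO in 9 of 22 cases and a larger one in 1, or 13 and 1 when adjusted over the list alone (median -0.48; adjusted p = 8.53e-16, and 0.0294 with an estimated correlation), with Socs3 at -1.20. Immediate early genes did so in 11 of 24 cases, 12 over the list alone (median -0.40; adjusted p = 5.86e-08, and 0.0294 with an estimated correlation), among them Fos (-0.60) and Fosl2 (-0.74); with any single library left out that count was between 5 and 9, lowest without WT control replicate 3, WT LPS replicate 1, KO LPS replicate 1 or KO LPS replicate 2. NF-kB inflammatory targets had smaller responses in 17 of 43 cases and larger ones in 0, or 23 and 3 when adjusted over the list alone (median -0.33; adjusted p = 8.53e-16, and adjusted p = 0.116 with an estimated correlation), among them Tnfaip3 (-0.71), Nfkb2 (-0.85), Traf1 (-0.62) and Nfkbia (-0.53). Cholesterol synthesis genes fell less in KO in 7 of 24 cases, 12 when adjusted over the list alone (median 0.39; adjusted p = 2.01e-12, and adjusted p = 0.122 with an estimated correlation), with Mvd at 0.95 and Hmgcs1 at 0.76; the count was 12 without KO LPS replicate 3.

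The other 4 lists of the interaction lost the call with an estimated correlation. Among interferon-stimulated genes no member passed, while the list had a median of 0.21 (adjusted p = 0.00416, and adjusted p = 0.888 with an estimated correlation); 6 members passed without KO control replicate 1. NRF2 targets had 3 of 20 members with a more positive and 1 with a more negative response (median 0.13; adjusted p = 0.00611, and adjusted p = 0.248 with an estimated correlation). Glycolysis had 4 of 18 with a more negative response, Pfkfb3 at -0.64 first (median -0.048; adjusted p = 0.00277, and adjusted p = 0.122 with an estimated correlation). OTU deubiquitinases had 1 of 13, Tnfaip3 (median -0.042; adjusted p = 0.0324, and adjusted p = 0.431 with an estimated correlation).

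Averaged over both treatments, 6 KO libraries were compared with 6 WT libraries, with treatment in the model. Hal (8.20), Timd4 (6.68), Rps24-ps3 (5.62), Depp1 (4.05), Rpl3-ps2 (2.97), Rpl3-ps1 (2.97), Rpl15-ps6 (2.85) and Rpl15-ps2 (2.49) were the most raised in KO. Olfr56 (-4.41), Mid1-ps1 (-2.13), Tdg (-2.08), Sirpb1a (-1.85), Mtus1 (-1.80), Sirpb1b (-1.61) and Nt5dc3 (-1.36) were among the most lowered. For each of these genes, KO and WT libraries did not overlap within either treatment, as the rule for naming required. Tlr4, the LPS receptor, was lower in KO at 19.5 ± 0.459 against 27.6 ± 1.14 FPKM without LPS and at 10.4 ± 0.521 against 15.4 ± 0.833 FPKM with LPS (log2 difference -0.58, SE 0.0338, adjusted p = 2.67e-08). In all 2915 genes differed, 1453 higher and 1462 lower, and 286 of them at least 2-fold (161 up, 125 down). Nlrp3 was higher (0.19, adjusted p = 0.00250), Il10 lower (-0.31, 0.00116), and Gsdmd lower (-0.22, 5.12e-05). Ifnb1 missed the threshold and passed as lower without KO control replicate 1 (-2.91) and in limma on log2(FPKM + 1) (-0.31), on log2(FPKM + 0.1) (-0.61), on quantile-normalized (-0.35) and on size-factor-scaled values (-0.37).

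Of the lists 8 of 29 passed over both treatments, 3 of them also with an estimated correlation: glycolysis, with 12 of 18 genes higher and 4 lower (median 0.25; 0.0183 with an estimated correlation), osteoclast genes, with 4 of 10 higher (median 0.34; 0.0467), and macrophage identity, with 12 of 24 lower and 2 higher (median -0.13; 0.0467). Interferon-stimulated genes were lower in 24 of 46 cases, 33 when adjusted over the list alone (median -0.31; adjusted p = 6.00e-09, and adjusted p = 0.584 with an estimated correlation), and in 40 without KO control replicate 1. Inflammasome genes were lower in 9 of 22 and higher in 3 (median -0.15; adjusted p = 0.00441, and adjusted p = 0.0506 with an estimated correlation). NRF2 targets were higher in 10 of 20 and lower in 2 (adjusted p = 1.61e-04, and adjusted p = 0.0758 with an estimated correlation), and heat shock genes higher in 7 of 14 (adjusted p = 1.61e-04, and adjusted p = 0.0758 with an estimated correlation). Alternative activation genes were lower in 7 of 18 and higher in 2, or as few as 1 with a library left out (adjusted p = 0.0132, and adjusted p = 0.0904 with an estimated correlation), with a median of -0.17 and a mean of 0.069.

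Genes that differed by at least 0.5 on the log2 scale over both treatments lay next to each other more often than in a random order, a test chosen after the values were seen. Of 17010 tested genes placed on the autosomes or chromosome X, 633 did so, and in 83 cases a gene and its next neighbour both did, against 23.5 on average in 10000 permuted orders (permutation p = 1e-04, one-sided, the smallest these can give). On chromosome 8 a stretch of 39 tested genes from Tex15 to Mtus1 held 18 of them, 8 higher and 10 lower in KO, among them Dusp4 (1.44), Slc7a2 and Mtus1. Timd4, Olfr56 and Tgtp2 lie within a stretch of chromosome 11, where 10 of 24 tested genes differed without LPS. Sirpb1a and Sirpb1b lie within a stretch of chromosome 3, where 8 of 20 did. The annotation of Olfr56 overlaps those of Gm12185, 9930111J21Rik1, Tgtp2, Ifi47 and Olfr1396, all among the 10 genes of chromosome 11. These were counted as separate genes and may share reads. The stretches of chromosomes 11 and 3 were found only without LPS, neither with LPS nor over both treatments.

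**Figure D4:**
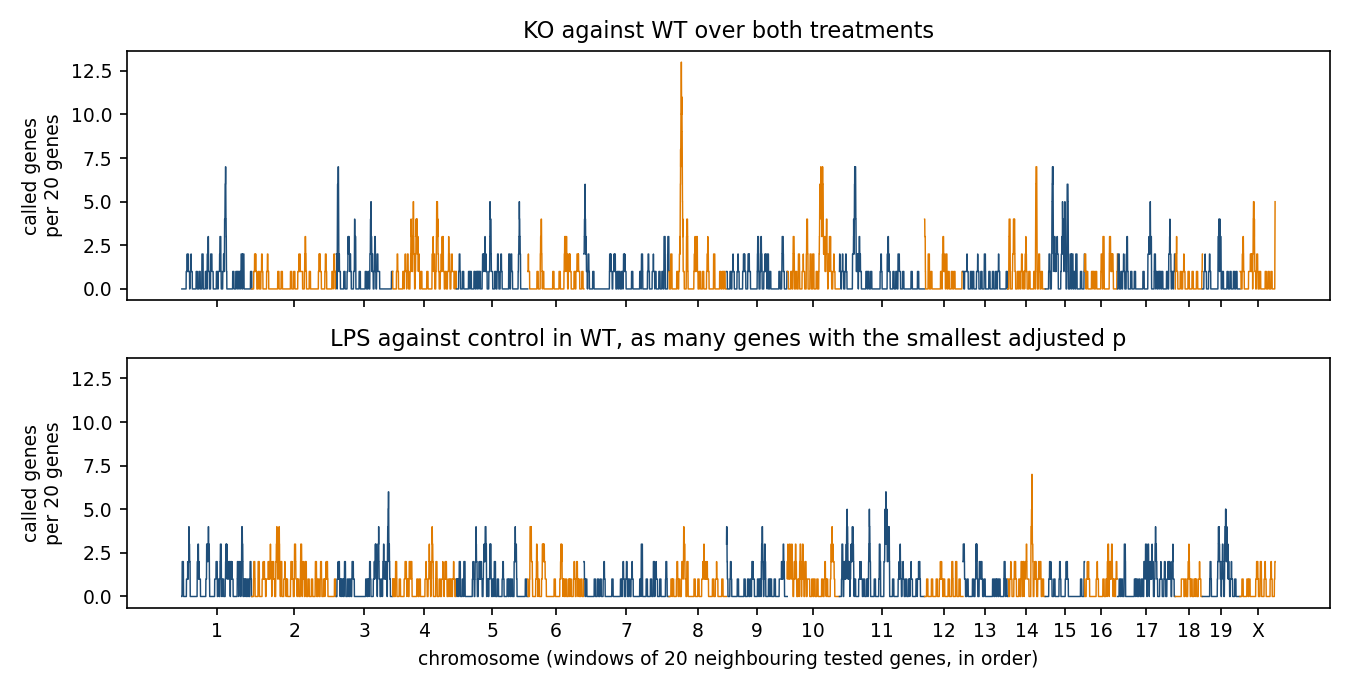
Lines count the chosen genes in each run of 20 neighbouring tested genes along the chromosomes. For KO against WT over both treatments these are the genes that passed the test with an absolute log2 value of at least 0.5. For LPS in WT they are as many genes with the smallest adjusted p, without a limit on the log2 value. The highest count was 13, on chromosome 8, between genotypes and 7 for LPS.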

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

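The tests of neighbouring genes, of response size, of pseudogene families and of other splits of the libraries in this part were written down only after the results had been seen; the tests of the difference in LPS response were planned.

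The LPS response of 829 genes differed between KO and WT in the test of the difference itself. Among named genes the log2 difference, KO minus WT, was 3.16 for Rps27rt, 2.30 for Sesn1, 1.94 for Pdlim4, 1.90 for Cdca7, 1.57 for Stard4, 1.49 for Rab3il1 and 1.38 for Cebpa. It was -2.98 for Angpt1, -2.54 for Timp1, -1.63 for Olr1, -1.56 for Tnc, -1.43 for Slc7a2, -0.63 for Il10 and -0.34 for Nlrp3. As given above, the calls of Rps27rt and Angpt1 were lost in most fits with 1 library left out. Those of Cdca7 and Nlrp3 were lost in several other settings. Some genes named as lower in KO without LPS also responded differently: Tmem254c (1.06), Ms4a4a (0.88), Fgl2 (0.87) and Pirb (0.18) gained on WT. Tdg (-0.61) fell further behind, and so did Mid1-ps1 (-1.32), which was named with LPS and over both treatments. The control libraries that picked the genes named without LPS also enter the difference in response. Their selection as lower genes can therefore by itself make that difference more positive. The median difference in response was -0.48 for negative regulators of TLR signalling, -0.40 for immediate early genes, -0.33 for NF-kB inflammatory targets, -0.048 for glycolysis, -0.042 for OTU deubiquitinases, 0.13 for NRF2 targets, 0.21 for interferon-stimulated genes and 0.39 for cholesterol synthesis genes.

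Other splits of the libraries were fitted to see how many calls a grouping without meaning gives. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split of the 6 libraries gave 10621 genes for LPS in WT and 9835 for LPS in KO (highest other split 0 in each), and 1709 genes for KO against WT without LPS and 2047 with LPS (highest other 1 in each). For the difference in LPS response, 2 of 60 splits drawn from 200 gave at least 829 genes, the real one included. The other one, with 2915 genes, exchanges genotypes within one treatment and so equals the comparison over both treatments, and the next highest was 395. In splits that mix the genotypes, the difference between genotypes adds to the spread within groups and lowers the calls. These splits therefore cannot exclude chance for the difference in response. For KO against WT over both treatments, 1 of 60 splits gave 2915 genes, the highest other was 829 by the same exchange and the next 515. This argues against a random grouping of these libraries, but cannot part genotype from animal if the libraries of a genotype came from 1 animal. For the 8 gene lists of the difference in response, 14 of 60 splits gave as many (highest 15), and for the 8 lists over both treatments 17 of 60 did (highest 14), so for the numbers of lists chance is not excluded.

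Genes that differed between genotypes crowd together on the chromosomes. Of the genes called over both treatments with an absolute log2 difference of at least 0.5, 83 neighbouring pairs were found against 23.5 in permuted orders on average, a permutation p of 1e-04, the smallest that 10000 permutations can give, which argues against random placement. An equal number of LPS genes, taken by smallest adjusted p in WT without a limit on the log2 change, gave 40 pairs. This was 1.71 times the permuted number, against 3.53 times between genotypes over both treatments. The sets were chosen by unlike rules, so the ratios are not strictly comparable. Taken by treatment, the ratio was 3.90 without LPS but 1.88 with LPS, and 1.998 for the difference in response, both near that of the LPS genes. Genes with overlapping annotations were counted as separate neighbours, so reads shared between them can add to the pairs. Neighbours that change together as members of a gene family were not set apart either. The excess over both treatments is consistent with stretches of the genome that come from another strain in one of the lines, as a hypothesis; genotypes were not read. The stretch of chromosome 8 holds 18 of the 633 genes (2.84%), so most calls lie outside it, and on chromosome Y 9 of 12 tested genes were called, 8 of them lower in KO. DNA kept around the targeted gene stays open. Of the 20 tested neighbours of Otud6a, 6 were called, all lower in KO, against 15.8% of the other genes on chromosome X. These are too few to decide (Fisher's exact test, two-sided p = 0.116). The 6 included the nearest tested gene on each side, Awat2 at -6.03 (edgeR adjusted p = 0.000812) and Igbp1 at -0.174 (edgeR adjusted p = 0.00145). The test of counts takes no account of size or distance.

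The LPS response was smaller in KO for most induced and most repressed genes, but not clearly for the most strongly induced ones. Sets were formed by the mean response of both genotypes, so that neither genotype selects them. Among well-counted genes, 1381 induced at least 2-fold had a median difference in response of -0.118 (95% bootstrap interval -0.135 to -0.0996, 70.2% below 0), and 1021 repressed at least 2-fold had 0.207 (0.188 to 0.229, 79.8% above 0). For the 190 genes induced at least 16-fold the median was -0.0451 (-0.174 to 0.0283, 53.2% below 0), an interval that includes 0. The bootstrap resampled genes, which share the same libraries, so its intervals do not measure the spread between libraries. Leaving out any 1 library gave, for the sets of at least 2-fold, -0.140 to -0.0956 and 0.160 to 0.281. A scaling error between libraries would move both sets the same way, so it is argued against by the opposite signs. A single share of cells that stay at the control profile would be the same for all genes. The induced genes need 11.2% of such cells (9.97 to 12.6 by bootstrap over genes, 9.14 to 13.4 with 1 library left out). The repressed genes need 6.44% (5.96 to 6.87 by bootstrap over genes, 4.93 to 9.64 with 1 library left out). The gap of 4.74 points was 3.26 to 6.06 with 1 library left out and 4.74 to 6.10 over 4 ways of scaling. As the gap kept its sign, it argues against a single share as the whole cause, but its spread between libraries was not tested. Genes induced 2- to 4-fold need 12.4% (10.99 to 14.3) and those induced at least 16-fold 3.18% (-1.98 to 11.7). Such a share together with an offset in scaling was not tested, and a smaller response per cell stays open.

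Genes and their processed copies changed in opposite directions between genotypes. In all 6 families with a processed copy changed at least 2-fold (Hdac1, Rpl15, Rpl3, Rps24 and Tdg among them) the parent was lower and the copy higher in KO. Reads shared between copies and parents, which a sequence difference between the lines could redirect, cannot be told apart from separate changes of the genes. Such sharing needs the copies to gain about what the parent lost; the median over the 6 families was 52.4% of the parent's loss, and the share lay between 50 and 150% in 3 of them. The copies gained 96.7% for Rpl3 (sum of parent and copies -0.016, SE 0.0211) and 111% for Rpl15 (sum 0.027, SE 0.0459), but 31.4% for Tdg (sum -0.91, SE 0.0351) and 37.0% for Hdac1 (sum -0.39, SE 0.0314). Copies under the filter were not counted, which keeps it open. For a difference in read mapping that reaches all copies, 298 processed copies named after a parent gene were counted. Of these, 7.38% were called over both treatments, against 17.2% of other genes (Fisher's exact test, two-sided p = 1.19e-06). With a mean of at least -1.59 log2 CPM the shares were 9.42% and 20.2%. The other genes include pseudogenes named otherwise, and many copies have few counts, which lowers their calls. The shares therefore cannot decide this question.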

How the results depend on the processing

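Counts divided by 4, fits without chromosome Y and the crowded stretch, and the agreement over well-counted genes were chosen after the data were seen; the other alternatives were planned. Numbers of genes called stayed within 1.5 times of those reported, apart from the following. With at least 5 FPKM in at least 3 libraries, LPS called 5928 genes in WT and 5754 in KO, since only 7247 genes were tested. DESeq2 called 1296 genes for the difference in LPS response; the cause was not tested. Leaving out 1 library gave 10059 to 10265 genes for LPS in WT, 9539 to 9784 in KO, 972 to 1165 and 1818 to 2637 for KO against WT without and with LPS, 2301 to 3038 over both treatments, and 518 (without KO LPS replicate 1) to 1126 (without KO LPS replicate 3) for the difference in response. With the replicate number as a block, which the check of residuals gave no ground for, the counts were 10502, 9967, 1294, 2359, 736 and 2703.

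The split into higher and lower genes moved with the scaling. In limma on log2(FPKM + 1), 19.6% of genes called for LPS in WT were higher without scaling and 50.5% on size-factor-scaled values; the shares were 74.5% and 39.3% for KO against WT with LPS and 71.5% and 29.6% for the difference in response. In edgeR, which also differs in test, input and filter, they were 47.7%, 50.2% and 41.4%.

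The slope of KO on WT responses was 0.466 with no filter, 0.928 with at least 5 FPKM, 0.866 with counts divided by 4, 0.919 on log2(FPKM + 1), 0.904 on log2(FPKM + 0.1), 0.919 on quantile-normalized and 0.909 on size-factor-scaled values, 0.920 over well-counted genes, and 0.672 to 0.779 with 1 library left out, so genes with few counts lower it. With an estimated correlation the lists called were 6 and 6 for LPS in WT and KO, 2 and 0 for KO against WT without and with LPS, 2 for the difference in response and 3 over both treatments. The lists of the difference in response numbered 7 to 13 with 1 library left out.

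Over the alternatives, 2779 of 2897 values of named genes kept direction and call, 74 lost the call, 18 gained one and 26 turned direction, none of these 26 with a call. A list that turned direction without a call in either fit was counted as unchanged. By this count 3128 of 3393 values of lists were unchanged, 127 lost the call, 125 gained one and 13 turned. On quantile-normalized values the set test turned, with mean log2 changes for LPS in WT of -0.53 for macrophage identity, 0.041 for glycolysis, -0.49 for oxidative phosphorylation, -0.42 for NRF2 targets, -0.42 for lysosome, 0.030 for proteasome and -0.73 for mitochondrially encoded genes, for LPS in KO of -0.048 for glycolysis, -0.40 for oxidative phosphorylation, -0.37 for lysosome and -0.57 for mitochondrially encoded genes, and of 0.038 for ribosomal proteins between genotypes with LPS. Of single genes near 0, Pycard over both treatments was 0.0032 with at least 5 FPKM, 0.041 on log2(FPKM + 1), 0.045 on log2(FPKM + 0.1) and 0.00898 on quantile-normalized values, and with LPS 0.028 and 0.032 on the unscaled values. Casp1 with LPS was 0.025, 0.025 and 0.013 on the +1, +0.1 and quantile-normalized values, and Il10 without LPS -0.000204 and -0.000752 on the +1 and +0.1 values. With 1 library left out, Pycard ranged from -0.14 to 0.0026 for LPS in WT, -0.13 to 0.019 between genotypes with LPS and -0.031 to 0.041 over both treatments, Nos2 from -0.20 to 0.13 without LPS and -0.15 to 0.017 over both, Il10 without LPS from -0.072 to 0.087, Nlrp3 with LPS from -0.0050 to 0.056, and the cell cycle list from -0.019 to 0.14 for the difference in response. The cause of these turns was not tested.

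Otud6a had no test in any setting; its mean count over the 6 WT libraries was 1.83, from 0.8 (without WT control replicate 3) to 2.2 with 1 of them left out. The list tests were not run in DESeq2. Depth limits genes of a few counts.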

Other observations

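Some components of the TLR4 pathway differed between genotypes, while the list did not pass (adjusted p = 0.112 without and 0.0818 with LPS). Without LPS, 5 of 29 genes were lower in KO and 1 higher; the number lower was 3 without WT control replicate 1, WT control replicate 3, KO control replicate 2 or KO control replicate 3. Tlr4 (-0.50, SE 0.0475), the kinase gene Irak4 (-0.65, SE 0.0714) and the adaptor gene Myd88 (-0.29, SE 0.0405) were lower and Traf3 (0.39, SE 0.0581) was higher. With LPS, 8 of 29 genes were lower and 3 higher; the number higher was as low as 1, without WT LPS replicate 2. Of all tested genes 8.41% differed without and 14.8% with LPS. Tlr4 (-0.66), Tbk1 (-0.25) and Map3k8 (-0.33) were lower and Ikbkg (0.25) higher. The co-stimulatory gene Cd86 was lower in KO without (-0.74, SE 0.0732) and with LPS (-0.60, SE 0.0659), in a list of 12 genes, of which 2 and 3 were lower (each as few as 1 with a library left out) and none higher, that did not pass in either case (adjusted p = 0.332 and 0.160).

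Of 24 genes of the unfolded protein and integrated stress response, 6 were lower and 5 higher in KO without LPS, and 5 were lower and 5 higher with LPS, and the list did not pass (adjusted p = 0.187 and 0.441); the number higher without LPS was 3 without any one of WT control replicates 1 or 2 or of the KO control replicates. Among the lower ones, the serine synthesis gene Phgdh had a log2 difference of -0.93 without and -1.03 with LPS, the asparagine synthetase gene Asns -0.68 and -0.69, and Psat1 -0.55 with LPS; Atf4 was lower without LPS (-0.40). The chaperone gene Calr was higher without LPS (0.29) and Herpud1 with LPS (0.59). Of 21 genes for migration, 6 were lower and 5 higher without LPS and 6 each with LPS; Mmp13 was lower in KO with LPS (-0.93) and Mmp14 higher without (0.60). Of 15 mitochondrially encoded genes, 3 were higher and 1 lower without LPS and 4 and 1 with LPS; the 4 were 1 without WT LPS replicates 1 or 3, 2 without KO LPS replicates 1 or 2 and 8 without WT LPS replicate 2. Of these genes mt-Rnr1, a ribosomal RNA, was lower in KO without (-0.59) and with LPS (-0.47), while mt-Cytb was higher (0.26 and 0.35). On chromosome Y, Ddx3y was lower in KO without (-0.78) and with LPS (-0.73), and so was Eif2s3y (-0.55 and -0.53), while Kdm5d did not pass in either (-0.18, adjusted p = 0.152, and -0.083, adjusted p = 0.533).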
